A study of Mus musculus with 12 samples.

How the data were processed

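Gene expression was measured by Affymetrix mouse exon array in bone marrow cells of female mice that had received 5-fluorouracil, after retroviral transduction with Hoxa9 and a second vector and after 3 or 4 weeks in culture with the cytokines IL3, SCF and IL6. RNA was labelled with biotin through a terminal labelling kit, with 1 array per sample. Per the labels, the authors processed the arrays with RMA in Affymetrix Expression Console, versions not given, and the deposited values are log2 values per exon-level probe set. The range of the values (0 to 14.93) and the near-identical array medians (6.302 to 6.345) were checked for that scale. Values are relative to the arrays of this set, and the number of arrays limits the precision.

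The table held 1256831 probe sets on 12 arrays, of which 20744 were at 0 on all 12 arrays and had no symbol listed. Of all probe sets, 318760 named 1 gene symbol (22296 symbols) and 6684 named several symbols and were left out of the gene values, as were 931387 with no symbol listed, those at 0 included. Probe sets were kept if their mean log2 over the 12 arrays was above 6.2592, the 50th percentile of all probe sets, which left 233798 named probe sets. Each gene's value was a median polish over its probe sets (at most 50 iterations, 2 genes without convergence), or the value of its probe set where it had 1 (2245 genes). This gave 20711 genes with a median of 8 probe sets each. Positions of the probe sets along the genes were not used here.

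Groups were fixed from the labels before the data were examined, as were the comparisons, the tests, the gene lists, the rule for naming genes and the alternatives, apart from the alternatives named below as chosen after seeing the data. The 3 conditions were HOXA9+MIY (Hoxa9 with an empty vector), HOXA9+MEIS1 (Hoxa9 with full-length Meis1) and HOXA9+MDHD (Hoxa9 with Meis1 lacking its homeodomain), each with 4 arrays, 2 at week 3 and 2 at week 4. A linear model over all 12 arrays with condition and week as terms was fitted with limma 3.58.1 (lmFit, eBayes with trend, two-sided) in R 4.3.3, with 8 residual and 4.09 prior degrees of freedom. Each pair of conditions and week 4 minus week 3 were tested as contrasts, and a model with interaction terms (6 residual degrees of freedom) tested whether each contrast differed between the weeks. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and those with at least 2-fold change were also counted. The probe sets of Hoxa9 and Meis1 were tested singly in a fit over all 318760 named probe sets. Where the mean of a group lay below the level of the filter, the fold of a named gene is given as at least that against the group's arrays at no less than that level. Errors after ± are limma's standard errors of the log2 difference unless given as SD. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots were made with matplotlib 3.10.9.

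Whether the numbers 1 and 2 in the labels pair the arrays across conditions was checked on the residuals after condition and week. The 12 matched pairs had correlations between -0.315 and -0.015, and 0 of 12 arrays correlated best with an array of their own week and number. Removing condition and week in itself lowers correlations within a week and raises those between weeks, so these values cannot be read against 0. Unmatched pairs of the same week and different conditions lay between -0.271 and 0.047. Matched pairs were no more alike than these, and the numbers were not used as blocks.

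The genes named per comparison were the 10 largest rises and the 10 largest falls among called genes with the same direction in all 4 matched pairs of week and number. For the weeks, the 6 pairs of the same condition and number took their place. Gene models without a given name and small RNAs were left out. From each gene list up to 4 called members with the largest change were taken, or the 2 with the largest change where none was called, and Hoxa9 and Meis1 always. The text gives those with the largest changes or the clearest known role and the rest as counts.

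The 26 lists, written from general knowledge, were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 26 lists of a comparison. They held markers of cells a marrow culture can contain (stem and early progenitor, primary granule and late stage neutrophil, monocyte and macrophage, dendritic and antigen presentation, mast cell and basophil, eosinophil, erythroid, megakaryocyte, B lymphoid, T and NK, stroma and endothelium). The others were HOX and TALE homeobox genes, genes tied to Meis1 or Hoxa9 in earlier work, cell cycle, cyclins with CDKs and their inhibitors, Myc and ribosome biogenesis, interferon response, Syk and ITAM signalling, cytokine receptors, hypoxia and glycolysis, apoptosis regulators, p53 response, immediate early and stress, Wnt and self-renewal, and microRNA genes and hosts. Some genes stand in several lists, Flt3 in 4 of them. Members were matched by symbol or by a single older symbol. Those without a probe set that named them alone and lay above the filter were not analysed here, nor was Elane, whose older symbol on the array names a second gene too. Mecom, with 2 older symbols on the array, was added as Evi1 in an alternative.

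The pipeline was tested on simulated data with the spread of these arrays. Of 50 genes each changed by 0.5, 1, 2 and 3 on the log2 scale, 37, 49, 50 and 50 were called, with 8 false calls among 20711 genes (4.12% of the calls), and a shifted list was called while 0 of 10 unchanged lists were. The simulated genes varied independently of each other, so false calls of lists with correlated members were not tested. The correlation estimated on the arrays was 0.583 for the cell cycle and 0.461 for the late neutrophil list.

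The alternatives were no filter and a stricter filter (7.725, the 75th percentile), the mean of the probe sets, quantile normalization, median centring, eBayes without trend, array weights, no week term, a replicate block, the groups compared alone, each week alone, a 2-fold bound, an estimated correlation and fry for the lists, split HOXA9+MIY arrays for the similarity of both Meis1 effects, and leaving out each array in turn. Those chosen after seeing the data were a random block for the same condition and number over the weeks, the number as a fixed term, cyclic loess, and leaving out both HOXA9+MDHD arrays of number 1 or of number 2, the 3 scalings for the gene lists, Evi1 in the lists, the lower bounds of folds and, for the overlap of calls, 100 simulations of unchanged groups and separate arrays of the shared condition. Other splits of the arrays into groups of the same size were fitted in the same way, all 35 for each pair of conditions and 100 drawn with a fixed seed for the weeks.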

Results

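RNA was profiled on 12 arrays from cultured mouse bone marrow cells that all carried a Hoxa9 vector, a homeobox gene that drives the growth of myeloid progenitors. With it came an empty vector (HOXA9+MIY), Meis1, a TALE homeobox partner of Hoxa9 (HOXA9+MEIS1), or Meis1 without its homeodomain, the part that binds DNA (HOXA9+MDHD). Each condition had 4 arrays, 2 after 3 weeks of culture and 2 after 4 weeks. The labels call the 4 experiments of a condition independent but do not state whether the week 3 and week 4 arrays come from the same cultures. Correlations between arrays over the probe sets lay between 0.9624 and 0.9823. Values are log2 gene values, n = 4 arrays per condition throughout.

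The vectors were first checked on the arrays. Hoxa9 stood at 13.29 ± 0.059 (SD) in HOXA9+MIY, 13.37 ± 0.080 in HOXA9+MEIS1 and 13.35 ± 0.123 in HOXA9+MDHD and was not called in any comparison, and 6 of its 7 probe sets had means above 11 in every condition. Meis1 was 7.31-fold higher in HOXA9+MEIS1 than in HOXA9+MIY (log2 2.87 ± 0.117, adjusted p = 1.16e-07) and 6.03-fold higher in HOXA9+MDHD (log2 2.59 ± 0.117, adjusted p = 7.75e-07). Of the 23 Meis1 probe sets, 10 were over 16-fold higher in HOXA9+MEIS1 than in HOXA9+MIY, by log2 4.64 to 7.06. In 4 of the 10 the HOXA9+MIY mean lay below 6.2592, the level of the filter on dim probe sets, so that the size of these rises is uncertain. Of the 10, 7 differed between the Meis1 vectors by at most 0.20 and were not called. The other 3 were 40.3-fold, 50.4-fold and 14.2-fold higher with full-length Meis1 (adjusted p = 5.53e-07, 1.07e-05 and 2.41e-09). In HOXA9+MDHD these 3 stood 3.09-fold, 1.83-fold (not called) and 5.31-fold above HOXA9+MIY, in the same order. At both weeks these 3 stood higher in the HOXA9+MDHD array of number 1 than in that of number 2, by log2 0.11 to 2.79, although at week 4 number 2 lay below 6.2592 in the 40.3-fold and 50.4-fold ones. Over the whole gene the difference between the Meis1 vectors was 0.28 ± 0.117 (adjusted p = 0.270), and it was called as the mean of the probe sets (0.90) and without both HOXA9+MDHD arrays of number 1 (0.51).

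**Figure D1:**
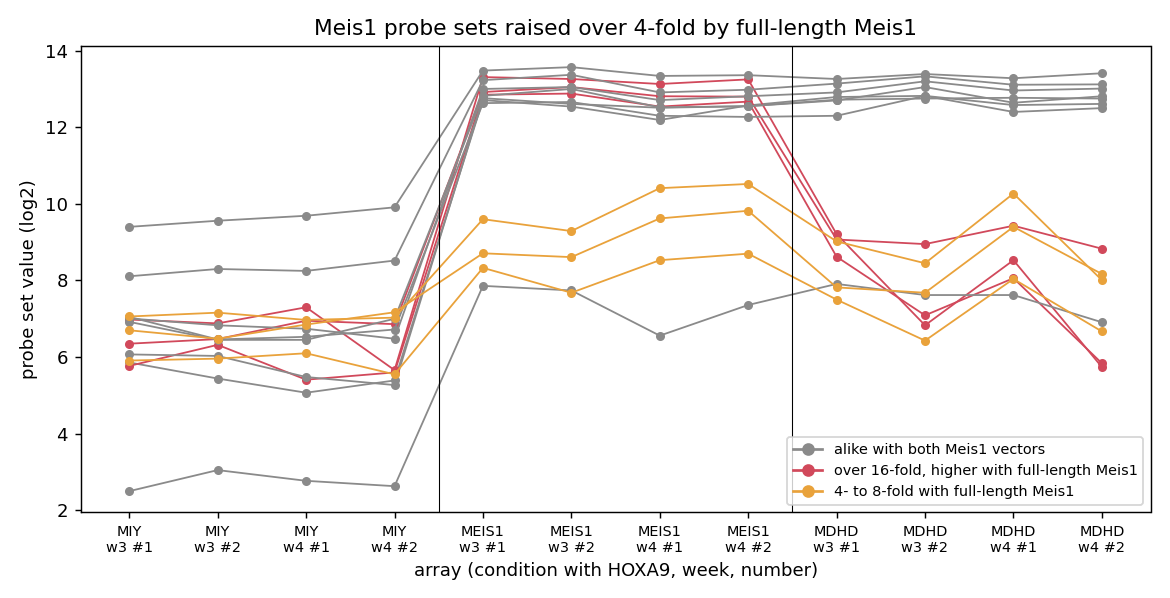
Values (log2) of the Meis1 probe sets raised over 4-fold by full-length Meis1, with 1 line per probe set and 1 point per array. The 7 grey probe sets raised over 16-fold by both Meis1 vectors differed between them by at most 0.20, while the 3 red ones were called higher with full-length Meis1.

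The comparison of HOXA9+MEIS1 with HOXA9+MIY asks what Meis1 adds to Hoxa9. In the stem and early progenitor list 9 of 23 measured genes rose and 2 fell (median log2 0.06, adjusted p = 0.401 with an estimated correlation). Of the late neutrophil list 21 of 26 genes fell, and of the monocyte and macrophage list 20 of 27 fell and 1 rose (adjusted p = 0.144 with an estimated correlation for each). Flt3, a cytokine receptor of early progenitors, rose 9.01-fold (log2 3.17 ± 0.172, adjusted p = 4.82e-07), from 6.79 ± 0.095 (SD) to 9.96 ± 0.155. S100a9, a calcium-binding protein of neutrophils and monocytes, was 17.0-fold lower (log2 -4.09 ± 0.453, adjusted p = 9.70e-05), and Ctss, a lysosomal protease of macrophages, was 11.0-fold lower (log2 -3.46 ± 0.180, adjusted p = 4.08e-07). Of 20711 genes 2246 were called, 1096 higher and 1150 lower with Meis1, and 352 of them changed at least 2-fold (122 higher, 230 lower). The direction was the same in all 4 matched pairs for 2226 of the called genes.

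The largest rise was that of Ddx4, an RNA helicase known from germ cells (26.5-fold, log2 4.73 ± 0.429). Beside Flt3 and Meis1 itself, the other large rises were those of Neto2, an accessory protein of kainate receptors (11.7-fold), Me1, the cytosolic malic enzyme (11.1-fold), the water channel gene Aqp8 (9.45-fold), the ATP-gated channel gene P2rx3 (7.73-fold), the glutamate receptor gene Gria2 (7.15-fold), the cation transporter gene Slc22a3 (6.67-fold) and the sodium pump gene Atp1b1 (5.65-fold). With no filter on dim probe sets Ddx4 was at log2 0.77, and with the stricter filter Me1 at 1.63, both called. Of the progenitor list 11 genes were called adjusted over the list alone. Risers were Flt3, Angpt1 (log2 1.59), the surface marker Cd34 (1.24) and the transcription factor Erg (1.18), whereas Ly6a, which encodes Sca-1, fell 8.06-fold and Prom1 fell 3.23-fold. Among genes tied to Meis1 or Hoxa9 in earlier work 8 of 24 rose and 4 fell (17 adjusted over the list alone), among them Id2, an inhibitor of basic helix-loop-helix factors, at log2 -1.48. Of the HOX and TALE genes, Pbx4 (log2 0.69), Pknox1 (0.69) and Pbx3 (0.58) rose beside Meis1 itself and none fell among 23 (4 adjusted over the list alone). Wnt and self-renewal genes gave 3 called members of 22, all higher (3 adjusted over the list alone), with Msi2 at log2 0.99 and Igf2bp3 at 0.79. Igf2bp3 was not called with the stricter filter on dim probe sets (log2 -0.03). Myc and ribosome biogenesis genes gave 4 called members of 23, all higher (5 adjusted over the list alone), with Odc1, the entry enzyme of polyamine synthesis, at log2 0.61.

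No late neutrophil gene was called higher (22 called adjusted over the list alone), and the collagenase gene Mmp8 and S100a8 were each 11.2-fold lower. Where a mean lay below 6.2592 the fold is a lower bound, with the dimmer arrays taken at no less than that level. Stfa2 was at least 12.0-fold and Ifitm6 at least 8.76-fold lower. Primary granule genes, of an earlier neutrophil stage, were lower in 6 of 13 (8 adjusted over the list alone, 1 of them higher), including Fcnb (log2 -2.44) and myeloperoxidase, Mpo (-1.77). Of the monocyte list 24 were called adjusted over the list alone. Csf1r, the M-CSF receptor, fell 7.94-fold (log2 -2.99 ± 0.179), Fn1 8.33-fold and F13a1 6.88-fold. The acute-phase gene Saa1, with 1 probe set, was at least 22.0-fold lower (adjusted p = 1.55e-04), Saa3 10.9-fold and the chitinase-like gene Chi3l3 10.5-fold. Klk1b1, of a kallikrein family whose members are alike in sequence, was 10.3-fold lower (log2 -2.66 with no filter on dim probe sets). Syk and ITAM signalling genes gave 7 lower and 2 higher among 22 (11 adjusted over the list alone), with the receptor genes Clec7a (log2 -2.04) and Fcgr4 (-1.50), the kinase gene Fgr (-1.13) and the adaptor gene Tyrobp (-0.59) lower. The eosinophil granule gene Prg2 fell 4.06-fold, the single called member of 8 on its list (2 adjusted over the list alone).

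**Figure D2:**
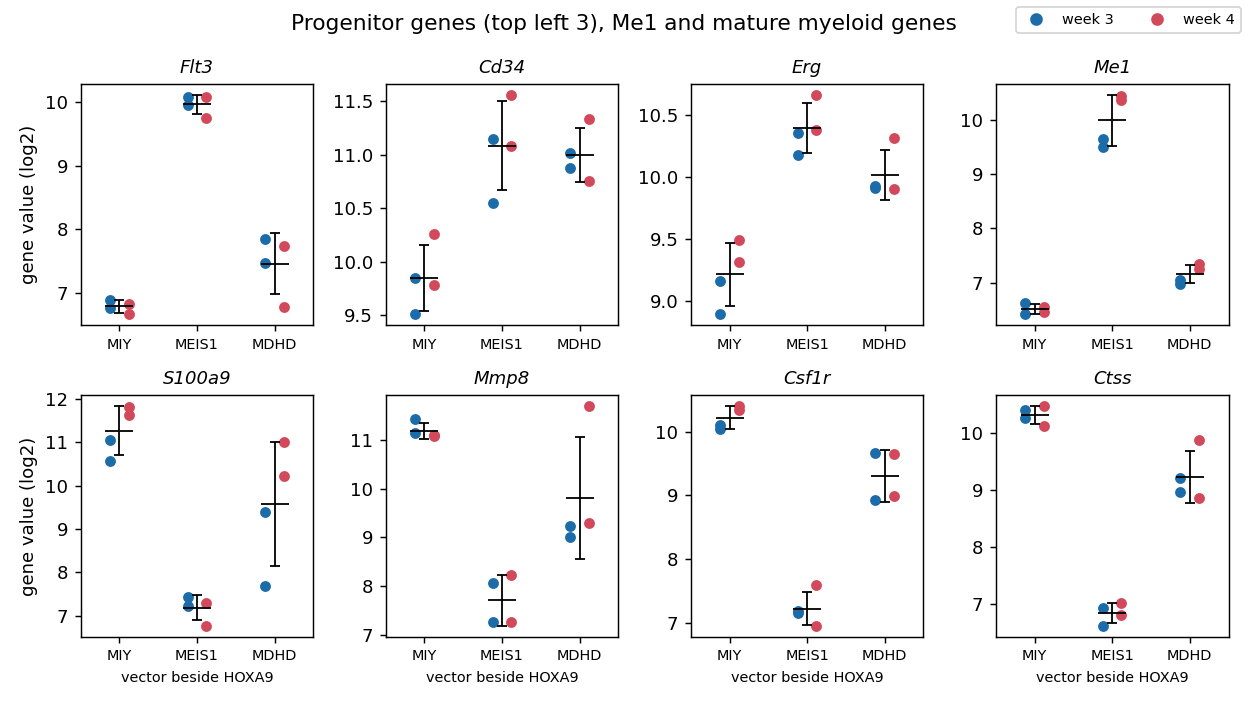
Gene values (log2, vertical axis) by vector beside Hoxa9, with 1 point per array coloured by week and the mean ± SD of 4 arrays in black. Flt3 and Me1 were higher with full-length Meis1 than in either other condition, Cd34 and Erg were higher with both Meis1 vectors than with the empty one, and the 4 mature myeloid genes of the lower panels were lowest with full-length Meis1.

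By camera 10 of the 26 lists were called in this comparison. The late neutrophil list (mean log2 -1.80, adjusted p = 7.04e-24), the monocyte list (-1.20, 1.10e-19), the primary granule list (-0.57, 0.0104), the Syk and ITAM list (-0.29, 7.39e-04) and the eosinophil list (-0.49, 0.0318) were lower. So was the cell cycle list (-0.10, 0.00289), with no called member among 34, 0 adjusted over the list alone and a mean of 0.01 on the week 3 arrays. The Myc list (0.15, 2.52e-05), the list tied to Meis1 or Hoxa9 (0.29, 0.00655), the progenitor list (0.24, 0.0160) and the Wnt list (0.13, 0.0246) were higher. With an estimated correlation 0 lists were called: adjusted p = 0.144 with an estimated correlation for the late neutrophil and monocyte lists, the lowest, 0.376 for the Syk and ITAM list and the list tied to Meis1 or Hoxa9, 0.401 for the progenitor list and 0.527 to 0.580 for the other 5. By fry, which tests whether a list's genes move one way on balance, 9 lists were called. Not among them were the eosinophil (adjusted p = 0.0719 by fry), Myc (0.0504), Wnt (0.0504) and cell cycle (0.214) lists. The HOX and TALE, megakaryocyte and cytokine receptor lists were called by fry but not by camera. The camera call of the eosinophil list ended without the HOXA9+MEIS1 (mean -0.41) or the HOXA9+MIY (-0.32) week 4 replicate 1 array and with cyclic loess (-0.48). That of the cell cycle list ended without HOXA9+MIY week 4 replicate 1 (-0.06) and that of the Wnt list without HOXA9+MIY week 3 replicate 2 (0.11).

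The other 16 lists were not called by camera in this comparison. Fry did call the HOX and TALE (adjusted p = 0.0152 by fry), megakaryocyte (0.0016) and cytokine receptor (0.0175) lists. The adjusted p that follow are those of camera. For cell types, called members were 2 higher and 2 lower of 18 in the dendritic list (adjusted p = 0.809), 2 higher and 1 lower of 19 in the mast cell list (0.895), 1 higher of 14 in the erythroid list (0.325), 2 higher and 4 lower of 18 in the megakaryocyte list (0.112), 1 lower of 15 in the B lymphoid list (0.196), 1 higher of 16 in the T and NK list (0.532) and 1 higher of 15 in the stroma list (0.789). The counts adjusted over the list alone were the same for these 7. The remaining lists gave an adjusted p of 0.115 for the HOX and TALE genes, 0.634 for cyclins with 1 lower of 17 (0 adjusted over the list alone), 0.182 for interferon response with 2 higher and 3 lower of 29 (9 adjusted over the list alone) and 0.182 for cytokine receptors with 3 higher and 7 lower of 20 (11 adjusted over the list alone). Hypoxia and glycolysis gave 0.497 with 1 higher and 2 lower of 30 (3 adjusted over the list alone), apoptosis regulators 0.140 with 1 higher and 1 lower of 21 (2), p53 response 0.0780 with 2 higher of 18 (3), immediate early genes 0.0585 with 2 lower of 18 (2) and microRNA genes 0.995 with 0 of 3 (0). Mean and median had opposite signs in the dendritic, stroma, cyclin, cytokine receptor and microRNA lists. The count of 2246 genes fell to 904 with no week term, 917 on the week 3 arrays and 850 on the week 4 arrays, where 53, 54 and 49 of the 76 called genes named by the rule kept their call. On the week 3 and week 4 arrays the change was log2 at least 4.25 and 2.15 for Aqp8, -3.48 and -4.69 for S100a9, -2.75 and -4.03 for Chi3l3, -1.18 and -2.86 for Prg2 and -2.69 (not called) and -4.21 for Saa3. Saa1, with HOXA9+MEIS1 means below 6.2592 at both weeks, was lower by at least log2 3.87 at week 3 (not called) and 5.05 at week 4.

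The comparison of HOXA9+MDHD with HOXA9+MIY asks what Meis1 does without its homeodomain. Fewer genes passed the test than with full-length Meis1: 396 were called, 189 higher and 207 lower, and 68 of them changed at least 2-fold (33 higher, 35 lower). In the progenitor list 4 of 23 genes rose and 1 fell (adjusted p = 0.314 with an estimated correlation). Among them were Cd34 at log2 1.15 ± 0.176 (2.22-fold, adjusted p = 0.00816), Erg at 0.80 ± 0.101 (1.74-fold, adjusted p = 0.00370), Angpt1 at 1.34 ± 0.212 (2.53-fold, adjusted p = 0.00861) and, as the one that fell, Ly6a at -0.82 ± 0.147 (1.76-fold, adjusted p = 0.0167). Flt3 was at 0.67 ± 0.172 (adjusted p = 0.0748), not called. The largest falls were those of Prg2 (5.68-fold, log2 -2.51 ± 0.370, adjusted p = 0.00686), Ifitm6 (3.81-fold) and Retnlg (3.03-fold), the latter pair on the late neutrophil list.

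After Meis1, the largest rises were Slc16a12, a monocarboxylate transporter gene (5.30-fold, log2 2.41 ± 0.206), Gria2 (3.72-fold), the fatty acid receptor gene Cd36 (3.52-fold), the drug efflux pump gene Abcb1a (3.03-fold), Marveld2 (2.93-fold), the haemoglobin gene Hbb-b1 (2.91-fold), Ccdc80 (2.87-fold) and Stxbp6 (2.78-fold). Marveld2, Hbb-b1 and Ccdc80 lost their call without HOXA9+MIY week 3 replicate 1 (adjusted p = 0.0725, 0.102 and 0.0775) and without other single arrays, and Hbb-b1 was not called with no filter on dim probe sets (log2 0.89). Late neutrophil genes were lower in 7 of 26 with none higher (17 adjusted over the list alone), among them the lactoferrin gene Ltf (log2 -1.40). Monocyte genes gave 5 lower and 2 higher of 27 (16 adjusted over the list alone), with Ctss at -1.08 and Apoe at -0.72 against Cd36, which rose. Primary granule genes gave 2 lower of 13 (3 adjusted over the list alone) and the eosinophil list 1 lower of 8 (4 adjusted over the list alone, 1 of them higher). Of the progenitor list 10 genes were called adjusted over the list alone. Mecom, a member of that list and of the list tied to Meis1 or Hoxa9, stands on the array as Evi1 (log2 0.52, called) and was not counted. With it the progenitor list gave 5 higher of 24, and the list tied to Meis1 or Hoxa9 gave 5 higher of 25 and became called by camera (mean 0.18, adjusted p = 0.0207, adjusted p = 0.317 with an estimated correlation). The formyl peptide receptor gene Fpr1 (log2 -1.42, 1 probe set), Klk1b9 (-1.47) and St6gal1 (-1.37) also fell. Of the p53 list, Perp rose 2.03-fold.

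By camera 8 lists were called: late neutrophil (mean -0.84, adjusted p = 2.75e-15), monocyte (-0.34, 3.65e-07), primary granule (-0.42, 3.67e-05) and eosinophil (-0.56, 0.01) were lower. Myc and ribosome biogenesis (0.15, 3.97e-10), progenitor (0.22, 2.59e-04), Wnt (0.07, 0.0387) and mast cell (0.26, 0.0447) were higher. In the Myc list no member of 23 was called over all genes (8 adjusted over the list alone), in the Wnt list 1 of 22 was higher (1 adjusted over the list alone), and in the mast cell list 1 of 19 was lower (4 adjusted over the list alone). With an estimated correlation 0 lists were called: adjusted p = 0.314 with an estimated correlation for the late neutrophil, monocyte, primary granule, Myc and progenitor lists, 0.449 for the eosinophil list and 0.554 for the Wnt and mast cell lists. By fry 0 lists were called, while its test for change in either direction called 16. The mast cell call ended without either week 3 array of HOXA9+MDHD (0.14 and 0.25) or of HOXA9+MIY (0.22 and 0.27) and without HOXA9+MIY (0.29) or HOXA9+MEIS1 (0.26) week 4 replicate 1, its mean was 0.04 on the week 4 arrays, and it was not called with quantile normalization, median centring or cyclic loess (0.27 to 0.28). The Wnt call ended without HOXA9+MDHD week 3 replicate 2 (0.04) or week 4 replicate 1 (0.05) or HOXA9+MIY week 3 replicate 2 (0.05). Of the 18 lists not called in this comparison, those of the HOX and TALE, erythroid and stroma genes had a mean above and a median below 0.

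The count of 396 depended on single arrays. It was 992 without HOXA9+MDHD week 4 replicate 2, and 254, 228 and 186 without the week 3 replicate 1, week 3 replicate 2 and week 4 replicate 1 arrays of HOXA9+MDHD. It was 140, 175, 162 and 206 without the week 3 replicate 1, week 3 replicate 2, week 4 replicate 1 and week 4 replicate 2 arrays of HOXA9+MIY. On week 3 arrays it was 240 and on week 4 arrays 11, with no week term 37 and with the groups compared alone 162. It was 242 without both HOXA9+MDHD arrays of number 1, 1143 without both of number 2 and 612 with the random block. Of the 39 called genes named by the rule 27 kept their call on the week 3 arrays, 6 on the week 4 arrays, 5 with no week term, 20 with the groups compared alone and 18 without both HOXA9+MDHD arrays of number 1. Prg2 was at log2 -1.51 on the week 3 and -3.51 on the week 4 arrays, and Klk1b9 at -0.87 with no filter on dim probe sets. Along the 351 genes changed at least 2-fold by full-length Meis1, other than Meis1, the HOXA9+MDHD arrays stood at 45.0%, 41.2% and 49.6% of the full-length shift, and week 4 replicate 2 at 17.5%.

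The effects of both Meis1 vectors overlapped. Of the genes called in both comparisons with HOXA9+MIY, 147 were higher in both (10 if independent) and 171 lower in both (11.5 if independent). Lists of the same sizes by p from 100 simulations of unchanged groups sharing the HOXA9+MIY arrays had 91.9 genes higher in both on average (highest 110) and 91.8 lower in both (highest 120). No simulation called more than 1 gene in either comparison, so these lists held hardly any called genes. Opposite calls were 5, with Opn3, Per2 and Plcb1 higher with full-length and lower with deleted Meis1 and 1700024P16Rik and Ttpa the other way, all 5 named after their values were seen. Of the 396 genes called with deleted Meis1, 375 (94.7%) had the same sign with full-length Meis1, against 90.5% (highest 93.4%) in the simulated lists, and 246 had the larger change with it. With separate HOXA9+MIY arrays for each comparison 4 or 5 genes were called with deleted Meis1. Lists of the same sizes by p then shared 107 or 92 genes higher and 146 or 156 lower, and 86.4% or 84.3% had the same sign. Across the 20711 genes, which are not independent replicates, the covariance of the log2 changes was 0.0375 (jackknife SE 0.00921) and Pearson's r was 0.667. Unchanged groups sharing the same HOXA9+MIY arrays gave 0.00634 and 0.5 in 100 simulations (highest 0.00686 and 0.522). With the separate HOXA9+MIY arrays the covariance was 0.0331 or 0.0340 and r was 0.557 or 0.553, by which arrays went to which.

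**Figure D3:**
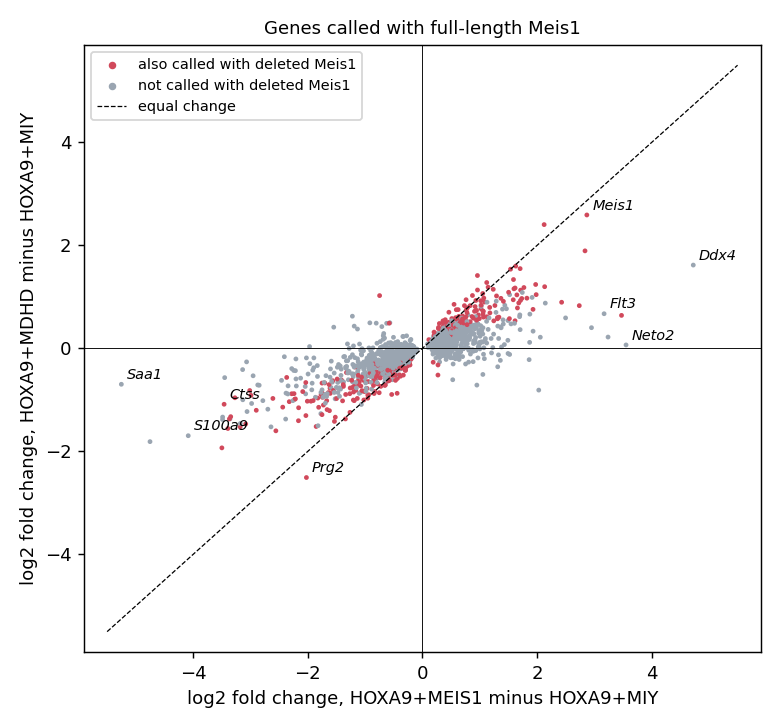
Log2 fold change against HOXA9+MIY with deleted Meis1 (vertical axis) and full-length Meis1 (horizontal axis) for the 2246 genes called with full-length Meis1, in red where also called with deleted Meis1. Both axes share the HOXA9+MIY arrays. Meis1 lies near the line of equal change, while Flt3 and Neto2 lie far below it.

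Full-length against deleted Meis1 compares vectors that differ, by the labels, in the homeodomain. Protein levels of both forms were not measured, so a difference cannot be laid on the homeodomain alone. Flt3 was 5.64-fold higher with full-length Meis1 (log2 2.5 ± 0.172, adjusted p = 6.95e-06), at 9.96 ± 0.155 (SD) against 7.46 ± 0.478. Neto2 was 11.2-fold higher (3.49 ± 0.228), Ddx4 8.62-fold (5.65-fold without HOXA9+MDHD week 4 replicate 2), Aqp8 8.10-fold, Rcn3, a calcium-binding protein gene of the secretory pathway, 7.16-fold, Me1 7.13-fold, P2rx3 5.85-fold, Ap1s2 4.23-fold and both Slc22a3 and Atp1b1 3.75-fold. With no filter on dim probe sets Ddx4 was at log2 0.41 and not called, and with the stricter filter Me1 was at 1.46. Of the monocyte and macrophage list 15 of 27 genes were lower with the full-length form and 2 higher (adjusted p = 0.0648 with an estimated correlation), with Csf1r 4.22-fold (log2 -2.08 ± 0.179, adjusted p = 4.61e-05), Ctss 5.19-fold and the lysozyme gene Lyz2 3.57-fold lower. The transmembrane glycoprotein gene Gpnmb was 6.99-fold and the apolipoprotein gene Apoc2 4.97-fold lower. Of 20711 genes 902 were called, 463 higher and 439 lower, with 164 changed at least 2-fold (54 higher, 110 lower).

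Of the monocyte genes 24 were called adjusted over the list alone, and late neutrophil genes gave 12 lower and none higher of 26 (18 adjusted over the list alone). Saa3 was 7.37-fold (4.51-fold without HOXA9+MDHD week 3 replicate 2), S100a9 5.24-fold and S100a8 4.44-fold lower. With means below 6.2592 in HOXA9+MEIS1, Saa1 was at least 13.6-fold lower (7.69-fold and 24.0-fold without HOXA9+MDHD week 3 replicate 2 and 1), the C-type lectin gene Clec4n at least 4.31-fold and Stfa2 at least 3.41-fold lower. Ly6a was 4.58-fold lower, while Cd93 (log2 0.46) was the other riser of the progenitor list beside Flt3, with 2 higher and 1 lower of 23 (4 adjusted over the list alone). The megakaryocyte list gave 4 lower and 1 higher of 18 (7 adjusted over the list alone), with the adhesion gene Selp (log2 -1.29) and the GTPase gene Rap1b (-0.30) lower. Syk and ITAM genes gave 3 lower of 22 (9 adjusted over the list alone), with Clec7a at -1.15. Among the partner genes Pbx4 (0.52) and Pknox1 (0.47) were higher with full-length Meis1, as was Igf2bp3 (0.79), which with the stricter filter was at 0.01 and not called. Evi1, the array's name of Mecom, was at -0.74 (called), with which the progenitor list gave 2 lower of 24.

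By camera 5 lists were called, all lower with full-length Meis1: monocyte (mean -0.86, adjusted p = 1.82e-20), late neutrophil (-0.96, 3.93e-15), megakaryocyte (-0.25, 2.75e-04), cell cycle (-0.09, 4.32e-04, with 0 of 34 members called and 0 adjusted over the list alone) and Syk and ITAM (-0.17, 0.00466). With an estimated correlation the adjusted p was 0.0520 for the megakaryocyte, 0.0648 for the monocyte, 0.281 for the late neutrophil, 0.597 for the Syk and ITAM and 0.872 for the cell cycle list, so that 0 lists were called, while fry called 3. Mean and median had opposite signs in the dendritic and erythroid lists and the test ranked the stroma list above other genes with a mean and a median below 0, none of these called. The Syk and ITAM call ended without HOXA9+MEIS1 week 4 replicate 1 (-0.14), and the cell cycle mean was 0.03 on the week 3 arrays. The count of 902 fell to 293 with no week term, 539 with the groups compared alone, 391 on the week 3 arrays and 221 on the week 4 arrays, where 28, 38, 33 and 30 of the 56 called genes named by the rule kept their call. On the week 3 and week 4 arrays the change was log2 2.32 and 3.89 for Ddx4, 3.68 and 2.36 for Aqp8 and, not called at week 3, -1.20 and -3.58 for S100a9 and -1.03 and -3.27 for S100a8. Saa3 (-2.86), Saa1 and Clec4n were not called at week 3 either. With HOXA9+MEIS1 means below 6.2592, Saa1 was lower by at least log2 3.83 at week 3 and 3.70 at week 4, Clec4n by at least 1.88 and 2.34 and Stfa2 by at least 0.69 and 2.86. Without both HOXA9+MDHD arrays of number 1 or of number 2 it was 3.53 or 2.15 for Rcn3, 3.86 or 2.35 for Ddx4 and -3.90 or -1.87 for Saa3, Clec4n was lower by at least 2.95 or 1.27, and without number 1 S100a9 (-2.16) and S100a8 (-1.87) were not called.

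**Figure D4:**
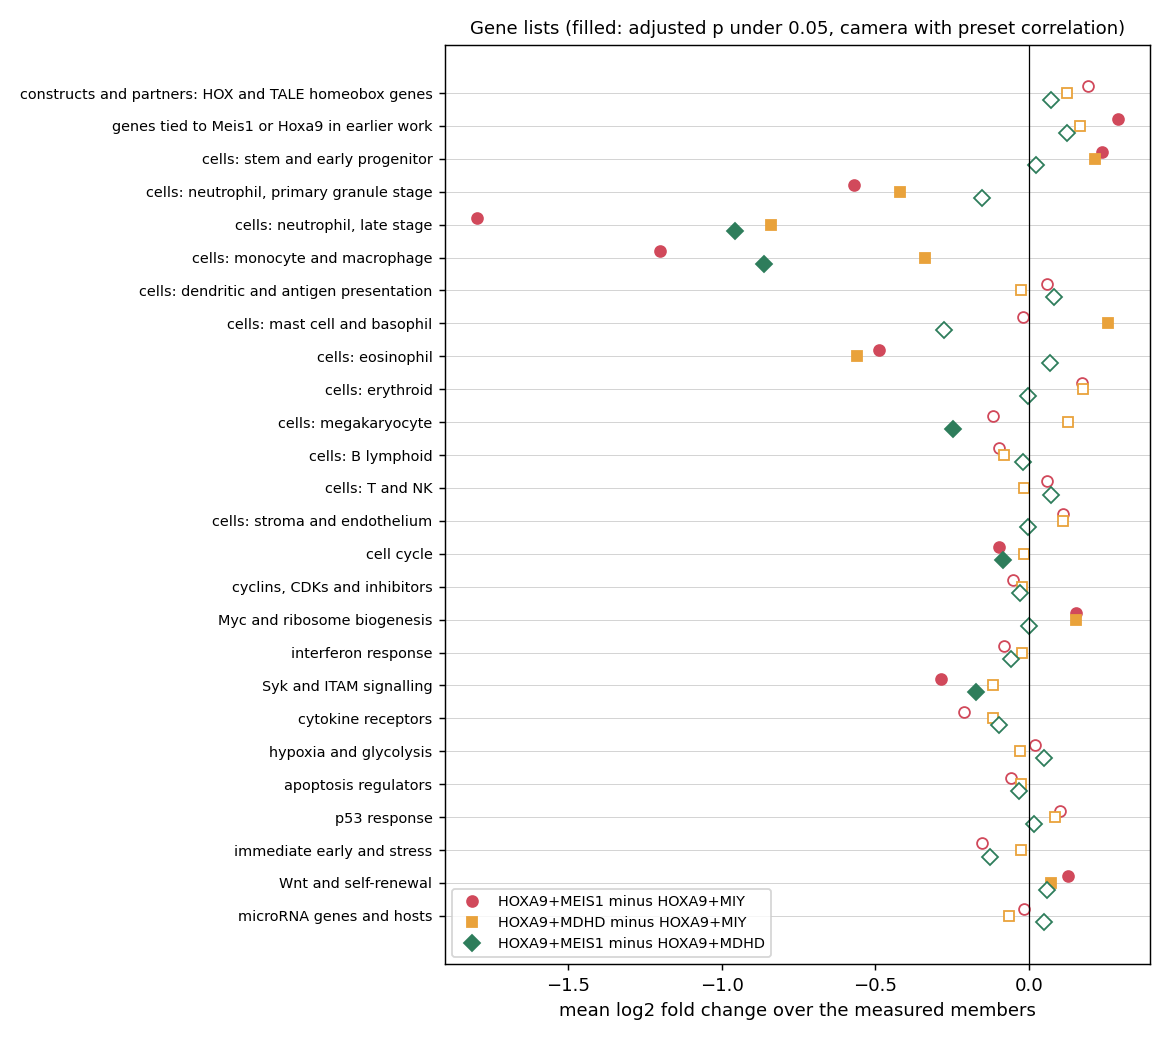
Mean log2 fold change over the measured members (horizontal axis) of each of the 26 gene lists in the 3 comparisons of conditions, filled where called by camera with the preset correlation. The late neutrophil list had a mean of -1.80 with full-length and -0.84 with deleted Meis1, and 0 lists were called with an estimated correlation.

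Between week 3 and week 4, over the 3 conditions, 22 of 30 hypoxia and glycolysis genes and 11 of 18 p53 response genes rose, and 23 of 23 Myc and ribosome biogenesis genes and 32 of 34 cell cycle genes fell. With an estimated correlation the adjusted p was 0.219 for each of the first 3 lists and 0.364 for the cell cycle list. Ddit4, an inhibitor of mTOR signalling, rose 4.96-fold (log2 2.31 ± 0.109, adjusted p = 1.22e-07), from 8.05 ± 0.212 (SD, n = 6) to 10.36 ± 0.226. The glycolytic enzyme gene Eno1 rose 3.46-fold (1.79 ± 0.104, adjusted p = 4.34e-07) and the cell cycle inhibitor Cdkn1a 2.90-fold (1.54 ± 0.066, adjusted p = 1.03e-07). Ccne1, the cyclin of entry into DNA replication, was 2.2-fold lower (-1.14 ± 0.073, adjusted p = 5.91e-07). Each of these 4 genes moved in the same direction in 6 of 6 pairs of the same condition and number. The naming rule required this of Ddit4 and Eno1, which are among the 10 largest rises. Neither Hoxa9 (-0.10 ± 0.039, adjusted p = 0.0624) nor Meis1 (0.02 ± 0.096, adjusted p = 0.896) was called.

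Of the hypoxia and glycolysis list 1 gene fell (23 called adjusted over the list alone), and among the risers were Ankrd37 (4.38-fold) and Ndrg1 (3.13-fold) beside Ddit4 and Eno1. Other large rises were the inducible nitric oxide synthase gene Nos2 (5.74-fold), Fam162a (4.6-fold, 3-fold with no filter on dim probe sets), Clec2d (4.19-fold), Lrrc32 (3.97-fold), the haem oxygenase gene Hmox1 (3.35-fold) and the glucocorticoid-induced gene Tsc22d3 (3.20-fold). In the p53 list 1 gene fell (13 called adjusted over the list alone) and Trp53inp1 (log2 1.44) and Btg2 (1.30) rose beside Cdkn1a, and the immediate early list gave 9 higher and 2 lower of 18 (11 adjusted over the list alone), with Atf3 (1.18) and Egr1 (1.02). The immediate early mean moved little in HOXA9+MIY, from 8.611 and 8.623 to 8.672 and 8.715. It went from 8.39 and 8.218 to 8.828 and 8.573 in HOXA9+MEIS1 and from 8.256 and 8.296 to 9.096 and 8.868 in HOXA9+MDHD. The list member Hspa1a stood high in week 4 replicate 1 of HOXA9+MEIS1 (10.732) and HOXA9+MDHD (9.8), which adds to the means of these arrays. In week 4 replicate 2 it stood at 7.581 and 7.881, and in HOXA9+MIY at week 4 at 7.254 and 7.067. The Myc and ribosome biogenesis list (23 adjusted over the list alone) held Nol5, which encodes Nop58, at log2 -1.03, and the nucleolar gene Gnl3 at -0.98. In the cell cycle list none rose (33 adjusted over the list alone), and of the cyclin list 5 rose and 5 fell of 17 (10 adjusted over the list alone), with the inhibitor Cdkn1b at 1.14 and E2f3 at -0.64. Late neutrophil genes gave 11 higher and 1 lower of 26 (12 adjusted over the list alone), with Il8rb, the gene of the chemokine receptor Cxcr2, 2.96-fold and Ly6g 2.5-fold higher. The list mean rose from 9.684 and 9.853 to 10.323 and 10.148 in HOXA9+MIY and from 8.897 and 8.589 to 9.272 and 9.893 in HOXA9+MDHD. In HOXA9+MEIS1 it showed no clear rise, with 8.221 and 8.251 at week 3 and 8.017 and 8.335 at week 4. Mast cell genes gave 4 lower and 2 higher of 19 (6 adjusted over the list alone), with the IgE receptor gene Fcer1a 4.18-fold lower, and Tph1, of serotonin synthesis, was 3.62-fold lower (log2 -1.02 with the stricter filter on dim probe sets). Other large falls were Cd27 (3.21-fold), the replication origin gene Orc1l (2.74-fold) and Bex6 (2.72-fold).

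**Figure D5:**
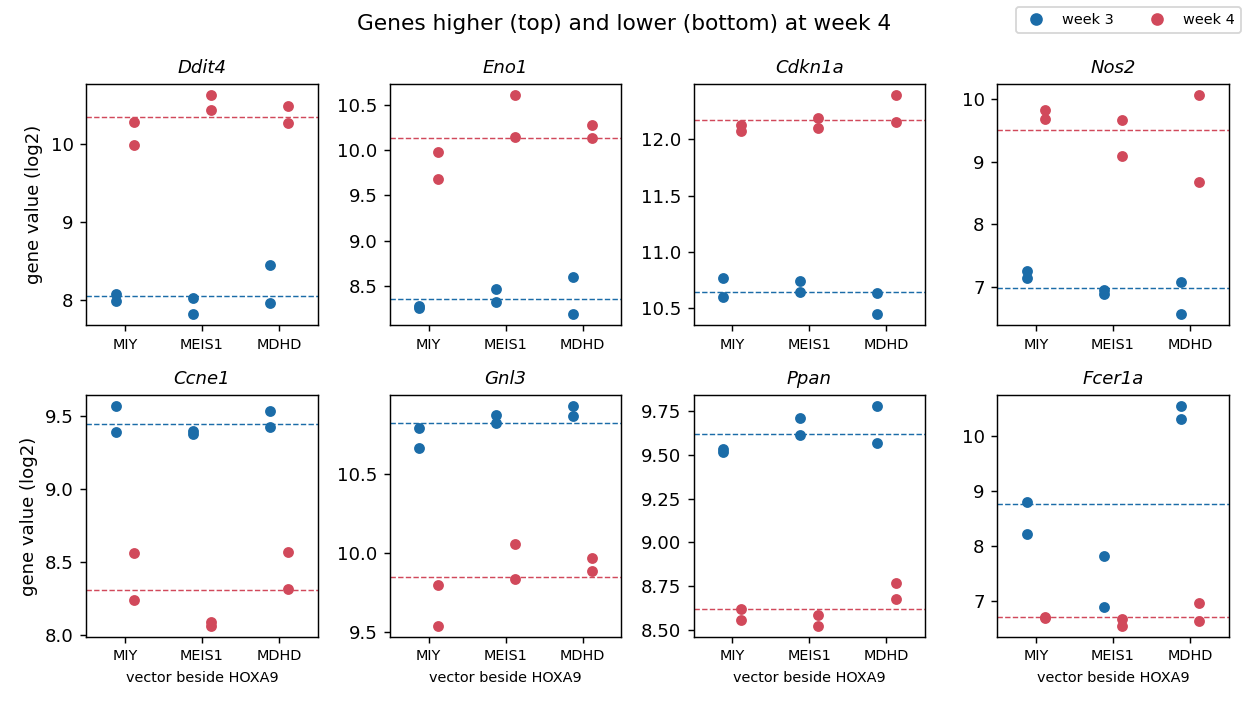
Gene values (log2, vertical axis) by vector beside Hoxa9, with 1 point per array coloured by week and dashed lines at the mean of the 6 arrays of each week. The 4 upper genes were higher and the 4 lower genes were lower at week 4, and Fcer1a stood highest in HOXA9+MDHD at week 3.

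In all, 8241 genes were called between the weeks, 2426 higher and 5815 lower at week 4 (29.4% higher), but 135 changed at least 2-fold (75 higher, 60 lower). The split depended on the scaling, with 41.9% higher after median centring, 46.2% after quantile normalization and 51.2% after cyclic loess. By camera the hypoxia list (mean 0.59, adjusted p = 7.01e-15), the p53 list (0.49, 9.14e-07), the late neutrophil list (0.42, 2.01e-04), the immediate early list (0.39, 0.00432), the list tied to Meis1 or Hoxa9 (0.12, 0.0412) and the megakaryocyte list (0.16, 0.0499) were higher. The Myc list (-0.64, 1.67e-13) and the cell cycle list (-0.44, 2.96e-11) were lower. In the list tied to Meis1 or Hoxa9 9 members rose and 4 fell of 24 (13 adjusted over the list alone), and in the megakaryocyte list 4 rose of 18 (3 adjusted over the list alone). The call of the list tied to Meis1 or Hoxa9 ended without HOXA9+MEIS1 week 4 replicate 2 (0.10) or week 3 replicate 1 (0.11) or HOXA9+MDHD week 4 replicate 1 (0.10), and with median centring (0.17). That of the megakaryocyte list ended without HOXA9+MEIS1 week 3 replicate 1 (0.15), week 3 replicate 2 (0.16) or week 4 replicate 2 (0.15), without replicate 2 of HOXA9+MIY at either week (0.15), and with the 3 scalings (0.20 to 0.22). The other 6 kept their direction and call with each of these scalings, with means of 0.59 to 0.72 for hypoxia, -0.64 to -0.46 for Myc and -0.44 to -0.27 for cell cycle. With an estimated correlation 0 lists were called: adjusted p = 0.219 with an estimated correlation for the hypoxia, Myc, p53 and megakaryocyte lists, 0.354 for the list tied to Meis1 or Hoxa9, 0.364 for the cell cycle list and 0.459 for the late neutrophil and immediate early lists. Fry called 10 lists, but not the late neutrophil list (adjusted p = 0.077 by fry). Among the 10 were lists that camera did not call. These were the microRNA (mean -0.67, adjusted p = 2.25e-05 by fry), Wnt (-0.13, 0.0128) and dendritic (0.14, 0.044) lists. Of the lists not called, the mast cell list had a mean of -0.21 with a median of 0.00 and the cyclin list a mean above and a median below 0, and by camera the mast cell, progenitor (-0.08) and HOX and TALE (-0.02) lists ranked on the higher side of all genes.

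Whether a Meis1 effect differed between the weeks was tested with interaction terms. By limma 0 genes were called for HOXA9+MEIS1 against HOXA9+MIY (smallest adjusted p 0.119), for HOXA9+MDHD against HOXA9+MIY (0.409) and for HOXA9+MEIS1 against HOXA9+MDHD (0.0594). At an unadjusted p under 0.05 there were 1345, 997 and 1551 genes, where chance gives 1036. With array weights 9 genes were called for the first.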

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

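The 3 tests on carry-over at Meis1 probe sets and both tests of a wrong or mixed HOXA9+MDHD array were chosen only after the result was seen.

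At Meis1 probe sets higher with full-length than with deleted Meis1, the HOXA9+MDHD arrays of number 1 carried more signal than those of number 2, by log2 0.11 to 2.79 at the 5 of them. The share that carry-over of HOXA9+MEIS1 cells or RNA would need differed 20.7-fold between the 5 at week 4 and 101-fold at week 3. The highest week 4 shares, 55.5% and 70%, stood at probe sets also higher in HOXA9+MDHD than in HOXA9+MIY (limma adjusted p = 0.0425 and 0.00287). Signal raised by the deleted form more strongly in number 1 than in number 2 would add to those shares, while a rise alike in both would not. The 5 together therefore cannot decide on carry-over. At the 3 of them raised over 16-fold by full-length Meis1 the shares differed 1.03-fold at week 4 and 9.18-fold at week 3, so carry-over there may remain as a candidate explanation. The excess was not confined to such probe sets. At 1 of the 9 not called higher with full-length Meis1 than with the empty vector (6.71 against 6.86), number 1 stood at 8.60 and 8.32 and number 2 at 7.08 and 6.23 (weeks 3 and 4). Number 1 there lay above the highest HOXA9+MEIS1 array by 1.34 and 1.06 (SD of these arrays 0.62), which argues against carry-over at this probe set alone. It was picked from the 9 as the 1 over 2-fold higher in number 1 than in number 2 at both weeks, so part of the excess was built into the choice. The genes that rose at least 2-fold with full-length Meis1 (121 genes) leave it open too. Their median share was 36.8% (bootstrap 30.1% to 46.1%) at week 4 and 13.9% (6.2% to 22.0%) at week 3, against 3.4% and 4.18% at the 2 strongest probe sets. Genes that the deleted form raises more in number 1 than in number 2 would add to that share. The bootstrap drew genes, which are not independent, from 1 array of each number per week, so its intervals hold no spread between HOXA9+MDHD arrays. No biological explanation was tested.

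The HOXA9+MDHD week 4 replicate 2 array lay near the HOXA9+MIY arrays, at 17.5% of the shift along the 351 genes changed by full-length Meis1 against 41.2% to 49.6% for the other 3 arrays of its condition. Over all probe sets it correlated best with an HOXA9+MIY array (0.9795), but so did week 3 replicates 1 and 2 of HOXA9+MDHD (0.9805 and 0.9751). An HOXA9+MIY array under the wrong label is argued against by its Meis1 signal, which stood at a median of 98.2% of the other HOXA9+MDHD arrays over the 7 probe sets raised by both vectors. A mixture with HOXA9+MIY cells that gives this shift on the linear scale would hold 38.1% to 52.2% of HOXA9+MDHD cells, by which of the other arrays is mixed. It is argued against by the median of 98.2%, which less the SD over the 7 probe sets is 82.6%, although the dimmest of them stood at 56.8%. What stays open is a difference of these cells from the others of their condition, which the design does not name, so no biological explanation was tested.

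Between week 3 and week 4, 8241 genes changed, and the week 4 arrays had a smaller difference between the medians of named and unnamed probe sets (1.712 to 1.831) than the week 3 arrays (1.891 to 1.961). As the whole cause, a lower contrast of the week 4 arrays is argued against by 74.7% of the genes called keeping their call and sign after cyclic loess, which removes differences that depend on the level. The share of called genes that were higher moved from 29.4% to 51.2% with it, so that the scaling may account for part of the calls and for the uneven split. Time in culture stays open, and since the labels give no processing dates, a batch shared by the arrays of a week cannot be told apart from it.

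The similarity of the effects of both Meis1 vectors was tested with separate HOXA9+MIY arrays for each, which left 88.3% and 90.8% of the covariance, so the shared arrays are argued against as its whole cause. Other splits of the 8 arrays of each pair of conditions were fitted in the same way. For HOXA9+MEIS1 against HOXA9+MIY 1 of 35 splits, the real one, gave as many as 2246 genes (highest other 0), for HOXA9+MDHD against HOXA9+MIY 1 of 35 gave 396 (highest other 2) and for HOXA9+MEIS1 against HOXA9+MDHD 1 of 35 gave 902 (highest other 1). For the weeks 1 of 100 drawn splits gave 8241, and the highest other, with 5 of 6 arrays of each week in place, gave 3059. None of the other splits fitted gave as many genes as the real one. The real split is itself counted, so 1 of 35 and 1 of 100 are the smallest shares that could be reached. The splits also treat the arrays as independent, while the labels do not state whether arrays of both weeks come from the same cultures. Chance is therefore made less likely for these counts but cannot be excluded by the splits.

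Among the genes named by the rule, 22 of 558 groups of 4 arrays (3.9%) had an array far from the other 3. Chance gives about 1 in 20 for 4 values of a single normal distribution. These groups mix arrays of both weeks with no week term removed, so that rate is no exact yardstick here. In HOXA9+MDHD week 4 replicate 2, Bst1 (10.46), F13a1 (12.13), Il7r (7.91), Lyz2 (12.84), Mmp8 (11.7), Rap1b (12.13) and St6gal1 (8.57) stood above and Angpt1 (7.9) below the other arrays of the condition. In HOXA9+MDHD week 4 replicate 1, Erg (10.31), Rsad2 (9.69) and Zbp1 (9.86) stood above and Pfkfb4 (7.96) below them. In HOXA9+MDHD at week 3, H2-Ab1 (9.84) and Hoxb4 (7.09) stood low in replicate 1 and Car1 (5.92) in replicate 2. In HOXA9+MEIS1, Cd74 (6.62) and Lat2 (12.4) stood low in week 3 replicate 1 and Cd36 (7.62) in week 3 replicate 2, and Il1a (6.41) and Il6ra (8.96) stood high in week 4 replicate 2. In HOXA9+MIY, Mmp8 (11.44) stood high in week 3 replicate 2 and Pbx3 (8.71) low in week 4 replicate 2.

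Interaction terms were tested over each list with camera at the preset correlation, as the mean log2 effect at week 4 minus that at week 3, and none of the differences that follow was called with an estimated correlation. The effect of HOXA9+MEIS1 against HOXA9+MIY differed for the late neutrophil (-0.527), eosinophil (-0.607), cell cycle (-0.224), monocyte (0.269), dendritic (0.119), hypoxia (0.111), p53 (0.139) and immediate early (0.319) lists. That of HOXA9+MDHD against HOXA9+MIY differed for the late neutrophil (0.373), monocyte (0.349), hypoxia (0.187), apoptosis (0.12), p53 (0.224), immediate early (0.629), mast cell (-0.444), eosinophil (-0.6) and erythroid (-0.162) lists. That of HOXA9+MEIS1 against HOXA9+MDHD differed for the late neutrophil (-0.9), primary granule (-0.333), cell cycle (-0.234), immediate early (-0.31), mast cell (0.601) and dendritic (0.122) lists.

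Of 390087 probe sets that name no gene, 4305 were called between HOXA9+MEIS1 and HOXA9+MIY (2031 higher, 2274 lower), 631 between HOXA9+MDHD and HOXA9+MIY (531 higher, 100 lower) and 1600 between HOXA9+MEIS1 and HOXA9+MDHD (487 higher, 1113 lower).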

How the results depend on the processing

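The random block, the number as a fixed term, cyclic loess, the fits without both HOXA9+MDHD arrays of a number, the scalings of the lists and Evi1 in the lists were chosen only after the result was seen. The counts of genes stayed within 1.5 times under the other filters, the mean of the probe sets, the scalings and the variance settings in each comparison between conditions and between weeks. With a 2-fold bound they were 352, 68, 164 and 135 (HOXA9+MEIS1 against HOXA9+MIY, HOXA9+MDHD against HOXA9+MIY, HOXA9+MEIS1 against HOXA9+MDHD, weeks), a stricter criterion by construction. With no week term they were 904, 37 and 293 for the conditions, where the week adds to the spread, and with fewer arrays 917, 240 and 391 (week 3), 850, 11 and 221 (week 4) and, with the groups compared alone, 162 for HOXA9+MDHD against HOXA9+MIY and 539 for HOXA9+MEIS1 against HOXA9+MDHD. Leaving out 1 array gave 140 to 992 for HOXA9+MDHD against HOXA9+MIY. That count was 612 with the random block, whose estimated correlation was -0.123. It was 242 without both HOXA9+MDHD arrays of number 1 and 1143 without both of number 2, and the cause was not tested. Array weights called 9 genes for the week dependence of HOXA9+MEIS1 against HOXA9+MIY, and the cause was not tested.

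An estimated correlation called 0 lists for each pair of conditions and 0 for the weeks. It was 0.583 for the cell cycle, 0.461 for the late neutrophil and 0.267 for the monocyte list against the preset 0.01, but -0.027 for the megakaryocyte list. Fry called 0 lists for HOXA9+MDHD against HOXA9+MIY and 3 for HOXA9+MEIS1 against HOXA9+MDHD, and the cause of either difference was not tested. On the week 3 arrays the cell cycle mean was 0.014 for HOXA9+MEIS1 against HOXA9+MIY and 0.032 against HOXA9+MDHD, and on the week 4 arrays the mast cell mean was 0.036 for HOXA9+MDHD against HOXA9+MIY, the camera direction being reversed in each, and the cause was not tested. Igf2bp3 was at -0.03 and not called for HOXA9+MEIS1 against HOXA9+MIY with the stricter filter, which leaves fewer of its probe sets, against 0.73 to 0.96 and called under its other alternatives. Meis1 became called between HOXA9+MEIS1 and HOXA9+MDHD with the mean of the probe sets (0.901) and without both HOXA9+MDHD arrays of number 1 (0.51). A mean takes in the full size of the 3 Meis1 probe sets far higher with full-length Meis1 (log2 5.33, 5.66 and 3.82), to which a median polish gives little weight. The other 7 raised over 16-fold differed between the Meis1 vectors by at most 0.20. Hoxa9 became called between the weeks with array weights (-0.102) and the replicate block (-0.098). The cause of the calls under settings other than the mean was not tested. The correlation of both Meis1 effects was 0.557 and 0.553 with split HOXA9+MIY arrays, where fewer arrays enter each effect.

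Of the genes named by the rule, 60 of 76, 19 of 39, 35 of 56 and 87 of 94 kept their call whichever array was left out, in the same order of comparisons, and 76, 38, 56 and 87 kept it with cyclic loess. Signal over background limits dim probe sets.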

Other observations

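The simulated overlaps and the count of mast cell genes by condition and week were chosen only after the result was seen, as were the genes named here. With the deleted form of Meis1, 37 genes were called against both other conditions in opposite directions of the contrasts, so that HOXA9+MDHD stood apart from HOXA9+MIY and HOXA9+MEIS1 on the same side. Both comparisons use the HOXA9+MDHD arrays, and lists of the same sizes by p from simulated unchanged groups had 119 such genes on average. No simulation called more than 1 gene for HOXA9+MDHD against HOXA9+MIY or 3 for HOXA9+MEIS1 against HOXA9+MDHD. Those lists thus held hardly any called genes and cannot tell whether 37 is an excess. With separate HOXA9+MDHD arrays for each comparison 22 or 15 genes were called in opposite directions. Cd36, a receptor for fatty acids, stood at 9.42 ± 0.753 (SD, n = 4) in HOXA9+MDHD, 7.60 ± 0.192 in HOXA9+MIY and 8.10 ± 0.322 in HOXA9+MEIS1. Scin, an actin-severing protein of the gelsolin family, stood at 9.52 ± 0.728, 8.15 ± 0.772 and 7.96 ± 0.725 in the same order, and Evi1, a transcription factor of stem cells, at 7.56 ± 0.247, 7.04 ± 0.113 and 6.82 ± 0.025. Raet1e and Raet1d, genes of ligands for the NK cell receptor NKG2D, stood lower, by log2 -1.08 and -1.18 against HOXA9+MIY and with 1.52 and 1.42 in the contrast of HOXA9+MEIS1 with HOXA9+MDHD. Called against both with the same sign, so that deleted Meis1 lay between the other conditions, were 82 genes (26 higher and 56 lower in both contrasts). With separate HOXA9+MDHD arrays they were 105 higher and 168 lower or 12 and 28, by which arrays went to which, so their number is uncertain. The simulated lists had 0.45 genes higher and 0.53 lower in both contrasts on average (highest 2 and 3), with the limit given above.

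Of the 19 measured mast cell genes 9 had their highest mean in HOXA9+MDHD at week 3 and 4 in HOXA9+MIY at week 4. Fcer1a stood at 10.54 and 10.31 in HOXA9+MDHD, 8.22 and 8.80 in HOXA9+MIY and 7.82 and 6.89 in HOXA9+MEIS1 at week 3, and between 6.55 and 6.96 on the 6 week 4 arrays. The mast cell tryptase gene Tpsb2 stood at 9.72 and 9.53 in HOXA9+MDHD at week 3 and between 7.5 and 8.08 on the week 4 arrays. Over the mast cell list the effect of HOXA9+MDHD against HOXA9+MIY was lower at week 4 than at week 3 by log2 -0.44 (adjusted p = 3.23e-08 by camera, adjusted p = 0.189 with an estimated correlation).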
